A study of Mus musculus with 8 samples.

How the data were processed

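The study measured RNA levels in B16 cells, a mouse melanoma line that makes pigment, after treatment with the secreted guidance protein SEMA3E or with cytochalasin D, a drug that blocks the growth of actin filaments. Per the labels, total RNA was amplified into Cy3-labelled cRNA and each sample was hybridised to 1 array of a mouse oligonucleotide design read in 1 colour. The 8 arrays formed 4 groups of 2 biological replicates, labelled control at 0 h, SEMA3E at 2 h, SEMA3E at 8 h and cytochalasin D at 8 h. The medium contained serum, per the labels. All 8 arrays lay on 1 slide and carried 1 scan date, per the file headers, with each group in neighbouring positions, so position on the slide and group cannot be told apart.

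The authors deposited a scanner file for each array and a table with a value per gene name. Per the file headers, the scanner files were made with Agilent Feature Extraction 11.5.1.1, and their processed signal was an intensity on a linear scale, with background subtracted, trends across the array removed and small values replaced by surrogates, without scaling between arrays. The deposited table also held intensity on a linear scale with no scaling between arrays, since its column medians ran from 5.30 to 28.7. Of the table's values for the 20738 gene names with a single spot, 99.99% lay within 1% of that spot's processed signal, and the step that combined several spots was not stated. The scanner signals were used for the results, and the table as an alternative.

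Each array held 62976 spots, of which 1439 were control spots and were left out. Spots marked as non-uniform or population outliers in the files were set to missing, and repeated spots of a probe were averaged on the log2 scale, which gave 55698 probes. A probe entered the test when it had a value on all 8 arrays and was well above background, as the files mark it, on both arrays of at least 1 group. This left 24668 probes, after 238 probes had been lost to outlier marks. A gene with several such probes took the one with the highest mean, as 4813 genes did, and 18026 genes or transcripts were tested, 12073 of them with a proper gene symbol. Older gene names were replaced by current symbols through RefSeq identifiers, which 27673 of the probes matched, and 1300 of the 34834 gene names received a newer symbol. The headers name genome build mm9 but the files give no position for the probes used here, so no coordinates are given.

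Values were log2 of the processed signal minus each array's 75th percentile over the 18691 probes well above background on all 8 arrays. All values below are on this scale, so that a value of 0 is the 75th percentile of those probes and a difference of 1 is 2-fold. Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the spread, 4 residual degrees of freedom and 3.39 prior degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with two-sided tests. A difference is given with limma's moderated standard error as log2 ± SE, and a group's level as mean ± SD. For a gene that was above background on no array of 1 group, the fold was taken against a floor on each such array. The floor was the higher of the array's signal and the lowest signal marked as well above background on that array. The fold is written as at least where the lowest marked signal was used, and it does not allow for the spread between replicates. Otherwise it is the fold of the group means and no bound. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.

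The number of arrays, 2 per group, limits the precision of every value. The median standard error of a difference was 0.34 log2 units. Tested on simulated data with the spread of these arrays, the same fit called 0 of 50 genes put in at 2-fold, 16 of 50 at 4-fold, 37 of 50 at 8-fold and 48 of 50 at 16-fold in the comparison of SEMA3E at 8 h with control, with 2 calls among genes that were not changed. All 200 were put in together and 101 were called, which eases the adjusted threshold for each of them. A lone changed gene with the median standard error would need a difference of 4.33 log2 units. The simulated genes were also drawn independently, without patterns that arrays share across genes. These shares can thus be too high for the comparisons below, where few or no genes passed. Between 37.8% and 48.2% of the spots on an array were well above background and no spot was saturated. Of the 28 pairs of arrays, 0 had identical signals.

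The comparisons were each treatment with control, cytochalasin D with SEMA3E at 8 h, and SEMA3E at 8 h with 2 h. The comparisons, the test, 22 gene lists, the cell type markers and the rule for naming genes were chosen before the data were examined. For each gene list with at least 5 genes tested, limma's camera test with a preset correlation between genes of 0.01 asked whether its genes ranked above or below all other genes, with Benjamini-Hochberg adjustment over the 22 lists of a comparison, and was repeated with the correlation estimated from the data. The result of 1 list is not reported. The shift of a list is its mean log2 difference minus that of the other genes. For each gene list the members past the threshold were also counted with p adjusted over the list alone. Markers of fibroblasts, leukocytes and macrophages, keratinocytes and endothelial cells were measured as other cell types.

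Named genes were those past the threshold and separated between the groups, up to 8 in each direction against control and up to 4 in the other comparisons, or, where fewer than 4 passed, the 4 with the smallest p in that direction, given as not having passed. Added to these were up to 4 members with the smallest p from each list past the camera test and from the SRF-MRTF cytoskeletal targets, the melanocyte pigmentation genes and the semaphorins, plexins and neuropilins. Always named were Sema3e, Plxnd1, Nrp1, Mitf, Tyr, Tyrp1, Dct, Pmel, Srf, Actb, Actg1, Vcl, Ccn2, Ccn1, Egr1 and Fos. Nrp1 was not tested because its probe did not pass the filter. Transcripts without a proper symbol were tested and counted but passed over by this rule.

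Alternatives tried were normexp background correction with an offset of 50, quantile normalization, scaling to the median of all probes, no filter and a stricter filter on dim probes, every probe as its own unit, the mean of a gene's probes, outlier spots kept, the deposited table, an intensity trend in the variance prior, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were the 75th percentile over all probes, normexp with quantile normalization, and removal of each array's trend on probe GC content. No structure of batches beyond the slide was recorded, and scan date or slide could not be used as a block because there was only 1 of each.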

Results

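The series measured transcripts in B16 mouse melanoma cells, with 2 arrays for each of 4 groups: untreated control labelled 0 h, SEMA3E for 2 h, SEMA3E for 8 h, and cytochalasin D for 8 h. SEMA3E is a secreted semaphorin that binds the receptor plexin D1, and the study's title asks which transcripts this pair changes in these cells. Cytochalasin D stops actin filaments from growing. Both 8 h groups were compared with controls labelled 0 h, so time in culture was not matched in those comparisons, whereas the 2 treatments at 8 h were matched to each other.

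The cells expressed the melanocyte program and the receptor in every group. In control, the pigment cell genes Dct, Tyrp1, Pmel and Mitf had levels of 4.45 ± 0.35, 3.98 ± 0.09, 3.85 ± 0.07 and 3.33 ± 0.28 (SD, n = 2), all above the 75th percentile of detected probes. Plxnd1, which encodes plexin D1, lay at 3.18 ± 0.08, and Sema3e itself was near background at -7.35 ± 0.37. Signal at the 75th percentile of all spots was 59.3 and 61.1 on the SEMA3E 2 h arrays and 66.8 on cytochalasin D replicate 2, and between 111 and 154 on the other arrays. The negative controls of SEMA3E 8 h replicate 2 read 41.6 against 17.9 to 22.2 elsewhere, and the spike-ins of SEMA3E 2 h replicate 2 had a median coefficient of variation of 22.2%, with 214 outlier spots.

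Replicates were not always the closest arrays. Across genes, which are not independent replicates, control replicate 2 correlated at 0.993 with cytochalasin D replicate 1 and at 0.974 with control replicate 1, and control replicate 1 correlated at 0.987 with SEMA3E 2 h replicate 1. Of the 8 arrays, 3 had their own replicate as the nearest array. The control arrays differed by over 2-fold in 14.3% of genes, the SEMA3E 2 h arrays in 14.2%, the SEMA3E 8 h arrays in 9.65% and the cytochalasin D arrays in 8.76%.

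**Figure D1:**
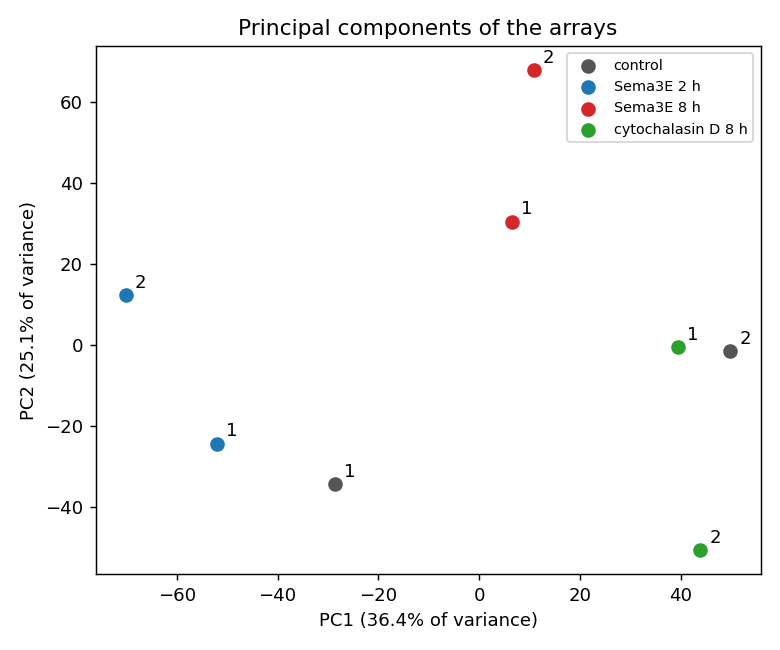
Principal components of the 8 arrays over all genes tested, with PC1 (36.4% of variance, arbitrary units) on the x axis and PC2 (25.1% of variance, arbitrary units) on the y axis; each point is 1 array, coloured by group and numbered by replicate. Control 2 lies beside cytochalasin D 1, while control 1 lies at -28.6 on PC1, on the side of the SEMA3E 2 h arrays.

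After 2 h of SEMA3E no gene passed the test, and the smallest p-values belonged to a mix of non-coding RNAs, a histone, a melanosome gene and Myc. Rmrp, the RNA of the RNase MRP complex, read -1.99 ± 0.67 with SEMA3E and -5.67 ± 0.09 in control (SD, n = 2), a difference of 3.68 ± 0.46 (SE). H1f4, a linker histone gene, differed by 2.58 ± 0.34 and Kcnq1ot1, a long non-coding RNA of an imprinted cluster, by 2.40 ± 0.36. Palld, which encodes an actin-binding scaffold, was above background on 1 of the 2 SEMA3E arrays and on no control array. It was 7.58-fold higher by the group means, and from 2.54 to 3.31 log2 units higher with 1 array left out. In the other direction, Rab27a, the GTPase that links melanosomes to their actin motor, read -4.79 ± 0.39 against -1.30 ± 0.02, a difference of -3.50 ± 0.42. The polarity gene Patj differed by -2.50 ± 0.36, Ovca2 by -2.16 ± 0.32, and the growth regulator Myc by -2.02 ± 0.34. All 8 had an adjusted p of 0.405, with both SEMA3E arrays on the same side of both controls. The other tested probe of Rab27a differed by -1.22 ± 0.40, and the other tested probes of Patj by -0.24, -0.47 and -0.39.

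No gene of the actin and pigment programs passed at 2 h, although Actb and Rab27a passed after normexp, Rab27a with scaling to the median of all probes, and Rab27a and Srf without SEMA3E 2 h replicate 1. After normexp all genes had a median of 0.39 at 2 h and 3391 of 3431 calls were higher, so the call of Actb as higher does not single it out. With normexp and quantile normalization 0 genes passed at 2 h. Values of single genes often rested on 1 array, since of 187 pairs of a named gene and a comparison, leaving out 1 array turned the sign in 32 and moved the value over 1.5 times in 77 others. The SRF-MRTF cytoskeletal targets, 29 of them tested, had 14 above 0 and 15 below, with Actb at 0.60 ± 0.24, Tagln at 0.58 ± 0.25, Srf at -1.05 ± 0.62 and Vcl at -0.58 ± 0.38. Srf lay at -2.13 without SEMA3E 2 h replicate 1 and at 0.03 without replicate 2. Ccn2, a connective tissue growth factor and YAP-TAZ target, differed by -1.12 ± 0.26 (adjusted p = 0.421) and Ccn1 by -1.34 ± 0.50. The melanocyte pigmentation genes had 15 of 27 above 0, with a median of 0.11 and a mean of -0.11, and held Mlana at 0.67 ± 0.25, Tyrp1 at 0.70 ± 0.27, Tyr at -0.75 ± 0.34 and the melanosome linker Mlph at -0.90 ± 0.29. Rab27a was the 1 pigmentation gene lower with p adjusted over the list alone, and Myc the 1 immediate early gene lower with p adjusted over the list alone, against 0 over all genes in either list. Fos differed by -0.76 ± 0.35 and Egr1 by 1.08 ± 1.51, with Egr1 at -0.06 without SEMA3E 2 h replicate 2 and 2.23 without replicate 1. Mitf, Dct and Pmel differed by 0.11, 0.03 and 0.46, and Actg1 by 0.27. Of the semaphorin family, Sema4g differed by 1.11 ± 0.42, Sema5b by 1.11 ± 0.52, Sema6b by 0.80 ± 0.40 and Sema3c by -0.88 ± 0.38, and Plxnd1 by -0.11 ± 0.26. Sema3e was above background on both control arrays and no SEMA3E 2 h array. It was 1.22-fold lower by the group means and lay at 0.05 without SEMA3E 2 h replicate 2. It passed as higher after normexp, where 3431 genes passed, so no firm direction is given.

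The oxidative phosphorylation genes passed the list test at 2 h, ranked above the other genes, but in 4 of 18 alternatives. Of 31 tested, 25 lay above 0, with a median of 0.37 and a shift of 0.26 (adjusted p = 0.0361), and the adjusted p was 0.867 with an estimated correlation. No member passed over all genes or with p adjusted over the list alone. The respiratory chain genes Ndufa1, Uqcrq, Ndufb3 and Cox6c differed by 0.93 ± 0.44, 0.78 ± 0.32, 0.71 ± 0.33 and 0.65 ± 0.30. The same list differed by a median of 0.38 between the 2 control arrays, where all genes differed by -0.07, and its shift was 0.01 (adjusted p = 0.765) without control replicate 2, -0.13 (adjusted p = 0.50) after normexp and -0.23 (0.757) with no filter. The call also ended without SEMA3E 2 h replicate 1 (0.337), either SEMA3E 8 h array (0.0816 each) or either cytochalasin D array (0.0516 each), with quantile normalization (0.357), normexp and quantile normalization (0.506), the median of all probes (0.294, list median -0.22), the 75th percentile over all probes (0.0903), the replicate block (0.0563) and the deposited table (0.232). The lowest adjusted p was 2.34e-04, without control replicate 1. By limma, 0 of 18026 genes passed at 2 h, 1710 had an unadjusted p under 0.05 (1007 higher and 703 lower, 901.3 expected by chance) and the smallest adjusted p was 0.405. That count was 787 without control replicate 2, 2936 without control replicate 1, 1109 without SEMA3E 2 h replicate 2 and 6898 after normexp. Without SEMA3E 2 h replicate 1, 417 genes passed (31 higher, 386 lower), and the count was 1 without control replicate 1, 3431 after normexp (3391 higher), 18 after scaling to the median of all probes and 28 from the deposited table.

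**Figure D2:**
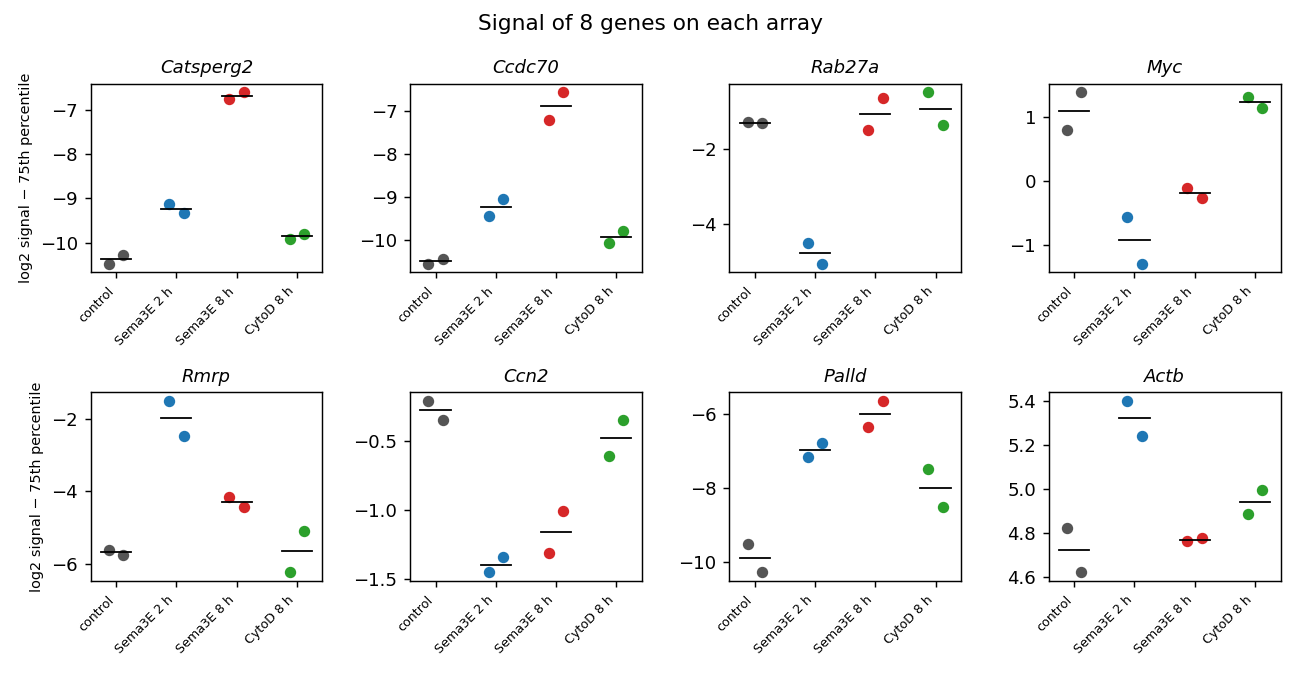
Signal of 8 genes on each array, as log2 signal minus the array's 75th percentile (y axis, log2 units) by group (x axis); points are single arrays and lines are means of 2. Catsperg2 reads -6.68 on average at SEMA3E 8 h and -10.38, under background, in control, and Rab27a reads -4.79 at SEMA3E 2 h and -1.30 in control.

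After 8 h of SEMA3E, 1 gene passed the test, with a higher signal, and its call depended on signals under background. Catsperg2, which encodes an accessory subunit of a sperm calcium channel, was at least 12.5-fold higher (adjusted p = 0.0157), above background on both SEMA3E 8 h arrays and on neither control array. Its level with SEMA3E was -6.68 ± 0.11 (SD, n = 2), its fitted difference was 0.62 after normexp and 0.32 with normexp and quantile normalization, and its other probe was above background on 0 of the 8 arrays. Next by p, without passing, came Ccdc70, at least 11.3-fold higher (adjusted p = 0.0526), Cfap57, a gene of cilia and flagella, 10.1-fold higher by the group means (0.0834), and Apobr, a lipoprotein receptor gene, at least 24.1-fold (0.0975), all 3 likewise above background on neither control array. The lowest p-values in the other direction belonged to Dars, an aspartyl-tRNA synthetase gene, at -1.73 ± 0.32 (adjusted p = 0.356), the small GTPase gene Rap1a at -1.37 ± 0.27 (adjusted p = 0.381), Cyp1a1 at -1.63 ± 0.38 (adjusted p = 0.593) and Zfp560, above background on neither SEMA3E array and at least 2.55-fold lower (adjusted p = 0.604). Limma called 1 of 18026 genes, with 1106 at an unadjusted p under 0.05, a count that was 537 without SEMA3E 8 h replicate 2, 2015 without control replicate 2, 634 after normexp and 2274 with scaling to the median of all probes. Catsperg2 passed in 9 of 22 alternatives, with adjusted p from 0.00484 to 0.973, and did not pass without control replicate 1 (0.142), control replicate 2 (0.211), SEMA3E 8 h replicate 1 (0.0598) or 2 (0.388), or cytochalasin D replicate 1 or 2 (0.119 each), nor with normexp, quantile normalization or an intensity trend. The count was 0 without control replicate 2 or any array treated for 8 h, 2 without either SEMA3E 2 h array, 7 with the replicate number as a block and 14 from the deposited table.

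The MAPK feedback genes, a list of genes induced by ERK signalling that includes inhibitors of it, ranked below the other genes at 8 h of SEMA3E. Of 15 tested, 12 lay below 0, with a median of -0.24 and a shift of -0.43 (adjusted p = 0.00531), and the adjusted p was 0.379 with an estimated correlation. Spry1, Dusp6 and Spred1, all inhibitors of this pathway, differed by -0.72 ± 0.30, -0.68 ± 0.30 and -0.43 ± 0.27, and the transcription factor gene Etv5 by -0.38 ± 0.30. The S phase and replication genes also ranked lower, with 20 of 29 below 0, a median of -0.10 and a shift of -0.30 (adjusted p = 0.0104), and the adjusted p was 0.635 with an estimated correlation. Their mean was -0.10, so most of this shift came from higher values of the other genes. The MAPK feedback genes had a mean of -0.23, so part of their shift came from the other genes too. Of all genes, 971 were higher and 135 lower at an unadjusted p under 0.05 by limma. Deviations from the gene means correlated with probe GC content at 0.17 and 0.31 on the SEMA3E 8 h arrays and at -0.28 and -0.06 on the controls. With the GC trend removed, 838 genes had an unadjusted p under 0.05 by limma, and the shifts were -0.32 (MAPK) and -0.26 (S phase). Slbp, which binds histone mRNA, differed by -0.59 ± 0.32, the replication licensing gene Mcm4 by -0.47 ± 0.30, Dtl by -0.57 ± 0.28 and Cdc45 by 0.54 ± 0.30. No member of either list passed over all genes or with p adjusted over the list alone. Both calls ended without control replicate 2 (adjusted p = 0.0875 each) and under scaling to the median of all probes (0.0604 each), and the S phase call also without control replicate 1 (0.0609), without SEMA3E 8 h replicate 1 (0.203) and with quantile normalization (0.242). The S phase shift was -0.08 with quantile normalization, -0.22 after normexp, -0.13 with both and -0.73 with no filter, and the MAPK shift -0.39, -0.32, -0.29 and -0.86. In other comparisons the MAPK list did not pass camera. Its shift was -0.31 (adjusted p = 0.364) at SEMA3E 2 h against control. With cytochalasin D against SEMA3E at 8 h, matched in time, it was 0.34 (adjusted p = 0.0692).

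Semaphorin, actin and pigment genes at 8 h of SEMA3E had values that did not pass. Sema4g differed by 1.82 ± 0.42, Sema5b by 1.27 ± 0.52, the plexin-regulated GTPase gene Rras by 0.81 ± 0.37 and Sema3c by -1.02 ± 0.38, within a family in which 18 of 28 tested genes lay above 0 (median 0.46, shift 0.14, adjusted p = 0.359). Plxnd1 differed by -0.05 ± 0.26 and Sema3e by -0.39 ± 0.38. The SRF-MRTF cytoskeletal targets had 17 of 29 above 0, a median of 0.10 and a shift of -0.06, and held Tagln2 at 1.43 ± 0.99, Itga5 at 1.1 ± 0.51, Myh9 at 0.71 ± 0.50 and Tpm4 at -0.32 ± 0.25. Tagln2 lay at -4.49 with outlier spots kept and without control replicate 1 and without control replicate 2 Myh9 lay at -0.13 and 1.56 and Itga5 at 0.30 and 1.90. Tagln2 lay at 0.69 without SEMA3E 8 h replicate 2 and 2.17 without replicate 1. Tagln2, Tpm2 and Sema5b were dim on every array, at -9.90 to -5.96, -7.46 to -5.82 and -8.79 to -6.44. Their differences in all comparisons thus rest on weak signals. Actb, Actg1, Srf and Vcl differed by 0.05, -0.08, 0.12 and -0.04. Ccn2 differed by -0.88 ± 0.26 (adjusted p = 0.682), Ccn1 by -0.65 ± 0.50, Fos by -0.04 ± 0.35 and Egr1 by 0.75 ± 1.51. Egr1 lay at -1.86 without SEMA3E 8 h replicate 1 and 3.36 without replicate 2, and Fos at -0.53 and 0.44. Among 27 pigmentation genes, 18 lay above 0 (median 0.04, shift -0.20), with Rab32 at -0.63 ± 0.31, Atp7a at 0.36 ± 0.28 and Trpm1 at 0.50 ± 0.37, and Tpcn2, above background on neither SEMA3E array, at least 1.43-fold lower. Mitf, Tyr, Tyrp1, Dct and Pmel differed by -0.25, 0.04, 0.11, 0.03 and 0.18. The Mitf value is that of its brightest probe, with which other Mitf probes did not move. In these 3 lists 0 genes passed over all genes or with p adjusted over the list alone, while in the interferon response list Oasl1, chosen after its values were seen, was the 1 gene higher with p adjusted over the list alone, at 1.44 ± 0.31.

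**Figure D3:**
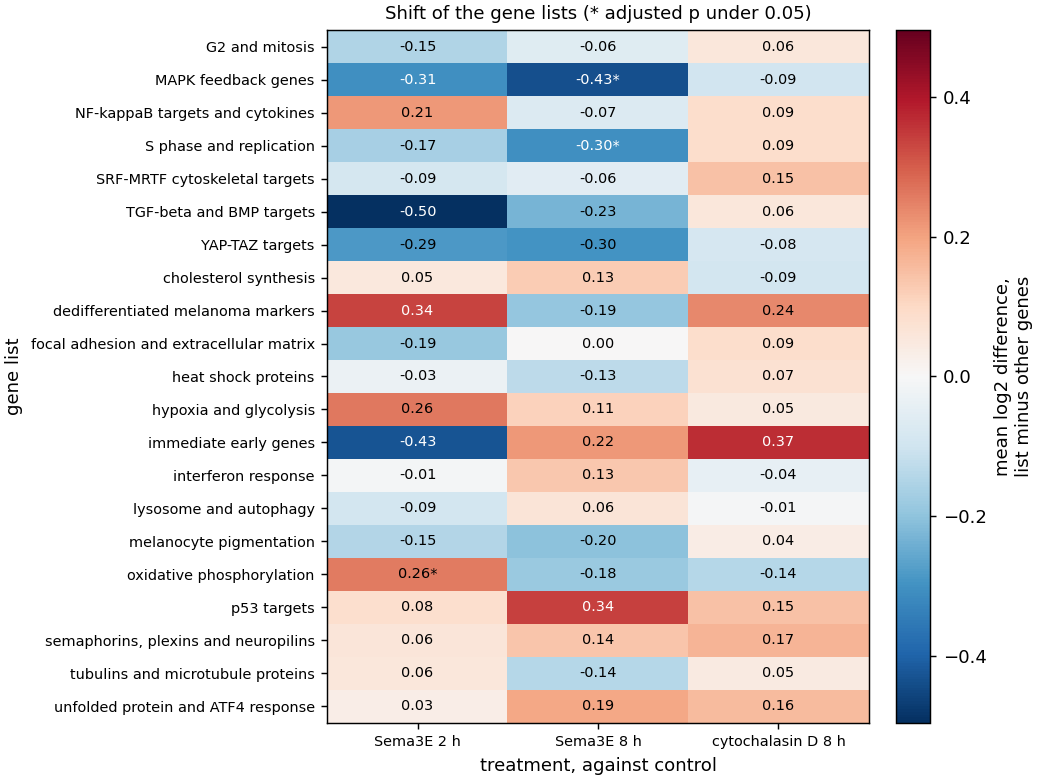
Shift of 21 gene lists (rows) in the 3 comparisons with control (columns), as mean log2 difference of the list minus that of the other genes, in log2 units by colour and number. An asterisk marks an adjusted p under 0.05 with the preset correlation, as for the oxidative phosphorylation genes at 0.26, the MAPK feedback genes at -0.43 and the S phase genes at -0.30, of which 0 passed with an estimated correlation.

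After 8 h of cytochalasin D no gene and no list passed, including the actin and SRF targets that the drug's action on filaments makes the natural question. The SRF-MRTF cytoskeletal targets had 19 of 29 above 0, a median of 0.13 and a shift of 0.15 (adjusted p = 0.392), with Myh9 at 1.04 ± 0.50, Tpm2 at 0.92 ± 0.52, Itga5 at 0.76 ± 0.51 and the filamin gene Flna at 0.42 ± 0.27. Without control replicate 1 and without control replicate 2, Itga5 lay at -0.04 and 1.56, Myh9 at 0.19 and 1.88, Tpm2 at 0.40 and 1.43, and Vcl at -0.48 and 0.60. Flna lay at 0.22 without cytochalasin D replicate 2. Actb, Actg1, Srf and Vcl differed by 0.22, 0.13, -0.05 and 0.06, and Ccn2, Ccn1, Fos and Egr1 by -0.20, 0.01, -0.11 and 0.13. Among genes with a proper symbol, the first in line by p were Palld and Prr15, the latter at 1.81 ± 0.48. Palld was above background on 1 cytochalasin D array and no control array, 3.73-fold higher by the group means. Its difference was 1.38 log2 units without cytochalasin D replicate 1. Pldi and Trim69 followed, but were above background on no array of either group, so no fold is given. In the other direction stood the embryonic globin gene Hbb-bh1, 5.26-fold lower by the group means, Dip2b at -1.70 ± 0.40, the ribosomal RNA Rs5-8s1 at -1.73 ± 0.41 and H1f4 at -1.46 ± 0.34. All 8 had an adjusted p of 1.0.

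Pigment and semaphorin genes did not pass with cytochalasin D either. Pigmentation genes had 18 of 27 above 0 (median 0.08, shift 0.04, adjusted p = 0.748), with Ap3b1 at 0.43 ± 0.27, Atp7a at -0.47 ± 0.28, Rab32 at -0.51 ± 0.31 and Tpcn2 1.96-fold lower by the group means. Mitf, Tyr, Tyrp1, Dct and Pmel differed by 0.13, 0.22, 0.32, 0.29 and -0.24. With the mean of a gene's probes Mitf lay at -1.20 and Tyr at -0.45, and in the deposited table Mitf, Tyr and Pmel lay at -0.61, -0.41 and 1.62. Without control replicate 1 Tyr lay at -0.21, and Mitf lay at -0.07 without control replicate 2 and -0.05 without cytochalasin D replicate 2. Sema4b differed by 1.16 ± 0.58, Sema5b by 0.81 ± 0.52, Sema3f by 0.50 ± 0.26 and Sema4g by -0.65 ± 0.42, in a family with 20 of 28 above 0 (shift 0.17, adjusted p = 0.392), and Plxnd1 differed by 0.36 ± 0.26 and Sema3e by 0.06 ± 0.38. Without control replicate 1 and without control replicate 2, Sema4b lay at 0.30 and 2.02, Sema5b at 1.33 and 0.29, and Sema3e at -0.20 and 0.33. No gene in these lists passed over all genes or with p adjusted over the list alone. By limma, 0 of 18026 genes passed, 439 had an unadjusted p under 0.05 where chance gives 901.3, and the smallest adjusted p was 0.193. The count under 0.05 was 206 without control replicate 1, 2045 without control replicate 2, 1193 without cytochalasin D replicate 1, 165 without replicate 2 and 229 with scaling to the median of all probes, so whether it lay below chance hinged on single arrays. The smallest adjusted p of any list with an estimated correlation was 0.895. The count of genes was 1 without control replicate 1 or either SEMA3E 2 h array, 2 with scaling to the median of all probes and 9 from the deposited table, and the count of lists was 1 without control replicate 2, the control array that lay next to cytochalasin D replicate 1.

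With time matched at 8 h, Catsperg2 was the gene that differed between the treatments. It was at least 8.32-fold lower with cytochalasin D than with SEMA3E (adjusted p = 0.0465), above background on both SEMA3E arrays and neither cytochalasin D array, and its fitted difference was -0.08 after normexp. Ccdc70 (at least 7.42-fold lower), Cfap57 (at least 8.86-fold lower) and the ribosomal RNA Rn18s (28.2-fold lower by the group means) had an adjusted p of 0.113. In the other direction Rap1a differed by 1.33 ± 0.27, Dars by 1.33 ± 0.32, N4bp2l2 by 1.32 ± 0.30 and Zfp715 by 1.28 ± 0.29, each with an adjusted p of 0.414. By limma 1 gene passed and 1985 had an unadjusted p under 0.05, of which 1575 were lower with cytochalasin D. The count under 0.05 was 583 without cytochalasin D replicate 2, 995 without SEMA3E 8 h replicate 2 and 1126 after normexp. Catsperg2 passed in 2 of 22 alternatives, with adjusted p from 0.0142 to 0.944, and in none of the 8 that left out an array, where adjusted p was 0.181 without either control, 0.0739 without either SEMA3E 2 h array, 0.122 and 0.576 without SEMA3E 8 h replicate 1 and 2, and 0.188 and 0.56 without cytochalasin D replicate 1 and 2.

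The S phase and replication genes ranked higher with cytochalasin D than with SEMA3E at 8 h. Of 29 tested, 22 lay above 0, with a median of 0.17 and a shift of 0.39 (adjusted p = 0.00409), and the adjusted p was 0.517 with an estimated correlation. Their mean was 0.18, so the shift also reflects lower values of the other genes. The replication genes Fen1 and Gins1 differed by 0.64 ± 0.28 and 0.55 ± 0.27, the methylation maintenance gene Uhrf1 by 0.91 ± 0.40 and Cdc45 by -0.70 ± 0.30, and no member passed over all genes or with p adjusted over the list alone. The call ended without SEMA3E 8 h replicate 1 (adjusted p = 0.0576), with quantile normalization (0.206) and with scaling to the median of all probes (0.064). The shift was 0.13 with quantile normalization, 0.15 after normexp, 0.17 with both and 0.59 with no filter. In the semaphorin family Sema4g differed by -2.46 ± 0.42 and was the 1 gene lower with p adjusted over the list alone, with Sema4b at 1.57 ± 0.58, Sema3c at 0.96 ± 0.38 and Plxnc1 at -0.67 ± 0.27. Chosen after their values were seen, Tgfb2 was the 1 YAP-TAZ target lower with p adjusted over the list alone, at -1.47 ± 0.29, and Psmb9 and Oasl1 the 2 interferon response genes, at -1.92 ± 0.33 and -1.37 ± 0.31, and none of these passed over all genes.

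Actin, pigment and receptor genes gave no call between the treatments at 8 h. Tagln2 differed by -1.90 ± 0.99, Mical2 by -0.54 ± 0.29, Flna by 0.44 ± 0.27 and Tagln by 0.41 ± 0.25, and the SRF-MRTF targets had 18 of 29 above 0 (median 0.10, mean below 0, shift 0.20, adjusted p = 0.26). Mical2 lay above 0 under quantile normalization, at 0.01, and Tagln2, which was dim on every array, at 0.54 with outlier spots kept, -3.20 without cytochalasin D replicate 1 and -0.60 without replicate 2. Actb, Actg1, Srf and Vcl differed by 0.17, 0.21, -0.17 and 0.11. Ccn2 differed by 0.68 ± 0.26, Ccn1 by 0.66 ± 0.50, Fos by -0.07 ± 0.35 and Egr1 by -0.62 ± 1.51. Egr1 lay at 1.99 without SEMA3E 8 h replicate 1 and -3.24 without replicate 2, and Fos at 0.42 and -0.55. Atp7a, Slc24a4, Gpr143 and Slc45a2 of the pigmentation list differed by -0.83 ± 0.28, -0.76 ± 0.44, -0.52 ± 0.29 and 0.49 ± 0.29, and Mitf, Tyr, Tyrp1, Dct and Pmel by 0.38, 0.19, 0.21, 0.25 and -0.42. Plxnd1 differed by 0.41 ± 0.26 and Sema3e by 0.45 ± 0.38. In the SRF-MRTF and pigmentation lists 0 genes passed over all genes or with p adjusted over the list alone.

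Between 2 h and 8 h of SEMA3E no gene passed, and Rab27a and H1f4 were among the smallest p-values, as at 2 h against control. Both comparisons use the same SEMA3E 2 h arrays, so this is no independent repetition. Rab27a read -1.06 ± 0.61 at 8 h against -4.79 ± 0.39 at 2 h (SD, n = 2), a difference of 3.73 ± 0.42 (adjusted p = 0.207). Catsperg2 was at least 4.23-fold higher at 8 h (adjusted p = 0.159) and Ccdc70 at least 3.29-fold higher (0.285), and Ovca2 differed by 2.36 ± 0.32 (0.285). H1f4 differed by -2.18 ± 0.34 (0.319), Kcnq1ot1 by -2.12 ± 0.36 (0.338) and D4Ertd681e by -2.14 ± 0.37 (0.338), and the embryonic globin gene Hbb-y was 3.22-fold lower by the group means (0.319). In the pigmentation list, Rab27a and its partner Mlph, at 1.26 ± 0.29, were the 2 genes higher with p adjusted over the list alone, against 0 over all genes, with Tyr at 0.79 ± 0.34 and Mlana at -0.65 ± 0.25. By limma 0 of 18026 genes passed, and 2091 had an unadjusted p under 0.05, with 937 without SEMA3E 8 h replicate 2, 845 with scaling to the median of all probes and 5341 after normexp. The count of genes that passed was 460 (448 higher, 12 lower) without SEMA3E 2 h replicate 1, 36 with scaling to the median of all probes and 20 from the deposited table.

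The oxidative phosphorylation genes ranked lower at 8 h than at 2 h of SEMA3E, with 26 of 31 below 0, a median of -0.34 and a shift of -0.44 (adjusted p = 7.52e-04), and the adjusted p was 0.728 with an estimated correlation. Ndufb3, Cox6c, Sdhd and Ndufa9 differed by -0.77 ± 0.33, -0.65 ± 0.30, -0.57 ± 0.26 and -0.53 ± 0.24, and no member passed over all genes or with p adjusted over the list alone. The shift was 0.04 (adjusted p = 0.948) after normexp, -0.06 (0.609) with quantile normalization and -0.01 (0.769) with both. The SRF-MRTF targets had 19 of 29 above 0 (shift 0.03), with Tagln at -0.79 ± 0.25, Actb at -0.55 ± 0.24, Myh9 at 1.14 ± 0.50 and Itga5 at 1.0 ± 0.51, and Actg1, Srf and Vcl at -0.35, 1.17 and 0.53. Srf lay at 0.09 without SEMA3E 2 h replicate 2 and at 2.25 without replicate 1. Plxna4, Plxna1, Plxnb1 and the plexin-binding adaptor gene Gipc1 differed by 1.32 ± 0.43, 1.31 ± 0.59, 1.13 ± 0.56 and 0.67 ± 0.38 and Plxnd1 by 0.06 ± 0.26, and Sema3e was above background on 1 array at 8 h and none at 2 h, so no fold is given. The genes Plxna4 and Plxna1 lay at -0.24 and -0.18 after normexp. Ccn2, Ccn1, Fos and Egr1 differed by 0.23, 0.69, 0.72 and -0.33, with Egr1 at -2.95 without SEMA3E 8 h replicate 1 and 2.28 without replicate 2, and Mitf, Tyrp1, Dct and Pmel by -0.36, -0.59, 0.01 and -0.28.

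The log2 differences of SEMA3E and cytochalasin D at 8 h from control correlated at 0.19 across 18026 genes (Spearman 0.14), and at 0.49 with no filter on dim probes. Of the 18026 genes, 54.0% had the same sign. Because both use the same controls, 100 simulations with unchanged groups gave a correlation of 0.50 ± 0.01 (SD), and the observed covariance of 0.0449 lay below the simulated 0.122 by a difference of -0.0770. The simulations drew each gene independently, with the same spread in every group. The replicate differences had an SD of 0.764 in control, 0.587 at SEMA3E 8 h and 0.603 with cytochalasin D. Patterns that arrays share across genes were left out, so the distance from 0.50 cannot be read as a test. With 0 genes called for cytochalasin D, shared calls say nothing, and the correlation ran from -0.01 without cytochalasin D replicate 1 to 0.61 without control replicate 2, with 0.39 without cytochalasin D replicate 2. With 1 array left out, simulations with unchanged groups gave 0.41 ± 0.01 for a cytochalasin D array and 0.67 ± 0.007 for a control array.

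Some markers of each of the other cell types were detected, and none was called in the comparisons with control. Of 10 markers each, the tested ones were Col1a1, Col1a2, Dcn and Postn for fibroblasts, Cd68, Csf1r, Adgre1 and Itgam for leukocytes and macrophages, Krt5, Krt14 and Trp63 for keratinocytes, and Pecam1, Kdr, Vwf and Egfl7 for endothelial cells. Above background on all 8 arrays were Col1a1, Col1a2, Cd68, Csf1r, Itgam, Trp63 and all the tested endothelial markers. Of all probes, 24668 of 55698 passed the filter, so these detections do not measure how pure the cells were. The median log2 difference from control at SEMA3E 2 h, SEMA3E 8 h and cytochalasin D 8 h was -0.37, -0.15 and -0.33 for fibroblast markers and 0.23, 0.58 and 0.05 for leukocyte and macrophage markers. It was 0.25, 0.27 and -0.27 for keratinocyte markers and 0.40, 0.43 and 0.13 for endothelial markers.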

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

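The tests of GC content, brightness, an exchange of arrays, carry-over, S phase and table spots, and the structural RNA and histone lists, were chosen after the patterns were seen, while the comparisons and the other lists were planned.

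Catsperg2 passed the test between the 2 treatments at 8 h, at least 8.32-fold lower with cytochalasin D (adjusted p = 0.0465). Its fitted difference of -3.17 rests on signals under background on both cytochalasin D arrays and was -0.08 after normexp. It passed in 2 of 22 alternatives, with adjusted p from 0.0142 to 0.944, and in none that left out an array (0.181 without either control, 0.0739 without either SEMA3E 2 h array, 0.122 and 0.576 without SEMA3E 8 h replicate 1 and 2, and 0.188 and 0.56 without cytochalasin D replicate 1 and 2). S phase and replication genes also differed between the 2 treatments, with a mean of 0.18, a shift of 0.39 (adjusted p = 0.00409) and 22 of 29 genes above 0, and the adjusted p was 0.517 with an estimated correlation. The shift was 0.13 with quantile normalization and 0.15 after normexp. Over the other alternatives its adjusted p ran from 1.12e-05 to 0.206, and it did not pass without SEMA3E 8 h replicate 1 (0.0576), with quantile normalization or with the median of all probes (0.064). Oxidative phosphorylation genes differed between the 2 times of SEMA3E, with a shift of -0.44 (adjusted p = 7.52e-04) and 26 of 31 genes below 0, and the adjusted p was 0.728 with an estimated correlation and from 3.45e-04 to 0.948 over the others, with a shift of 0.04 after normexp, -0.06 with quantile normalization and -0.01 with both.

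Control replicate 2 lay closer to cytochalasin D replicate 1 than to its own replicate, with a correlation of deviations from the gene means of 0.60 against -0.34 with control replicate 1. Deviations from a mean over the arrays correlate below 0 on average by construction, so these values are not to be read against 0. Removing each array's trend on probe GC content left 1.03 ± 0.003 of the excess of 0.60 over -0.34. Removing its trend on brightness left 0.996 ± 0.002 (bootstrap SD), and both argue against these trends as the whole cause. These SDs came from resampling genes and hold no spread between arrays. Over the 6 exchanges with an array of another group, the highest value of the lower new correlation was -0.17, for cytochalasin D replicate 2, where both new pairs correlated more than the labelled ones, -0.17 against -0.34 and 0.60 against 0.28, so an exchange stays open. A single wrong label needs no partner and stays open. A real difference between the 2 control cultures stays open too, and a dependence on the position of single arrays was not tested.

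RNAs that carry no poly(A) tail were looked at because Rmrp and H1f4 were among the smallest p-values at 2 h, and no test of these lists was run. The 11 structural RNAs, Rmrp among them, had medians of 1.35, 0.53 and -0.37 for SEMA3E 2 h, SEMA3E 8 h and cytochalasin D against control, and the 31 histone genes 0.65, 0.19 and -0.72, with 0 called. More cells in S phase would raise the replication genes with the histones, yet their median at SEMA3E 2 h lay -0.0402 ± 0.09 (bootstrap SD) from that of all genes. These genes thus showed no rise as a set. The SD came from resampling the genes of the list and holds no spread between arrays, so the explanation is not ruled out. Carry-over of such RNAs into the labelled sample stays open, since its test, in which the 2 lists lay on the same side of all genes at SEMA3E 2 h and with cytochalasin D by at least 0.402, was drawn up from the same values. The controls themselves differed for histones, at 0.48 and -0.65 relative to the mean of the arrays, so a difference between single RNA preparations stays open beside an effect of treatment. For the structural RNAs the controls lay at -0.06 and -0.71, and the SEMA3E arrays above both, at 0.93 and 1.37 (2 h) and 0.26 and 0.28 (8 h). The cytochalasin D arrays lay at -0.53 and -1.02.

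The deposited table gave calls that the scanner signals did not, 28, 14, 9, 13 and 20 in the 5 comparisons, of which 0, 1, 0, 1 and 0 were shared. A share of 0.930 of the called genes, 40 of 43, had a ratio of table value to spot mean that differed over 1.5-fold between arrays, against 26.1% of all genes compared and 55.4% of those with several spots. The 40 had several spots and the other 3 had 1, so lost spots do not bear on their own signals. Genes with several spots that are called in the table and not from the spots are picked by a difference between table and spots, so the share decides nothing for them, and whether spots were left out on some arrays stays open, as the step that combined spots was not stated. No biological explanation was tested for these calls, which concern the same hybridisations.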

How the results depend on the processing

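The 75th percentile over all probes, normexp with quantile normalization and the GC correction were chosen after the data were seen, and the other alternatives before. The cause was not tested for the changes below, except where the alternative itself changes how many genes or arrays are used. Of 4258 values recomputed for 187 pairs of a gene and a comparison, 3997 kept their direction and side of the threshold, 36 newly passed, 33 no longer passed, 126 with a value within 1 SE of 0 changed sign and 66 of the others turned in sign. Comparisons are with control unless another group is named, and cytochalasin D is at 8 h.

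With normexp, the genes called were 3431 (SEMA3E 2 h) and 0 (SEMA3E 8 h), and the lists called were 1 (cytochalasin D), 6 (cytochalasin D against SEMA3E) and 5 (SEMA3E 8 h against 2 h). Signs turned there for Sema3c 0.10 (SEMA3E 2 h), for Sema3e 0.0621 (SEMA3E 8 h), for Dip2b 0.16, Hbb-bh1 0.13, Sema4g 0.29 and Tpcn2 0.42 (cytochalasin D), for Mical2 0.18 and Tagln2 0.0352 (cytochalasin D against SEMA3E), for Catsperg2 -0.50, Ccdc70 -0.47, Itga5 -0.00647, Plxna1 -0.18 and Plxna4 -0.24 (SEMA3E 8 h against 2 h). With quantile normalization, the genes called were 0 (SEMA3E 8 h) and 0 (cytochalasin D against SEMA3E), and the lists called were 0 (SEMA3E 2 h), 6 (SEMA3E 8 h), 1 (cytochalasin D) and 3 (cytochalasin D against SEMA3E). There, signs turned for Actb -0.0329 and Actg1 -0.0309 (SEMA3E 2 h), for Mical2 0.0121 (cytochalasin D against SEMA3E), for Actb 0.0333 and Pmel 0.11 (SEMA3E 8 h against 2 h). With scaling to the median of all probes, the genes called were 18 (SEMA3E 2 h), 0 (SEMA3E 8 h), 2 (cytochalasin D), 7 (cytochalasin D against SEMA3E) and 36 (SEMA3E 8 h against 2 h), and the lists called were 0 (SEMA3E 2 h), 0 (SEMA3E 8 h), 1 (cytochalasin D), 0 (cytochalasin D against SEMA3E) and 2 (SEMA3E 8 h against 2 h). Sign changes there were Actg1 -0.32, Pmel -0.13 and Tagln -0.0159 (SEMA3E 2 h), Atp7a -0.80, Cdc45 -0.62, Itga5 -0.0609, Myh9 -0.45, Rras -0.35 and Trpm1 -0.66 (SEMA3E 8 h), Atp7a 0.16, Cdc45 0.29, Gpr143 0.46, Mical2 0.44, Plxnc1 0.31, Pmel 0.56 and Slc24a4 0.22 (cytochalasin D against SEMA3E), Vcl -0.0369 (SEMA3E 8 h against 2 h). Scaling moved the median log2 difference of all genes, from 0.06, 0.12, 0.03, -0.13 and 0.09 for SEMA3E 2 h, SEMA3E 8 h, cytochalasin D, cytochalasin D against SEMA3E and SEMA3E 8 h against 2 h, to -0.53, -1.04, -0.15, 0.85 and -0.48 with the median of all probes and to 0.39, 0.12, 0.23, 0.11 and -0.32 with normexp, so that the signs of single genes are relative to these.

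With the deposited table, the genes called were 28 (SEMA3E 2 h), 14 (SEMA3E 8 h), 9 (cytochalasin D), 13 (cytochalasin D against SEMA3E) and 20 (SEMA3E 8 h against 2 h), and the lists called were 0 (SEMA3E 2 h). On the other side of 0 were Actg1 -0.61, Sema3c 0.50, Tyr 0.31 and Vcl 1.17 (SEMA3E 2 h), Myh9 -1.05, Spred1 1.24 and Tagln2 -2.82 (SEMA3E 8 h), Plxnc1 0.0169, Pmel 1.32 and Tagln2 0.85 (cytochalasin D against SEMA3E), Actg1 0.67, Myh9 -0.57, Tyr -0.29 and Vcl -1.19 (SEMA3E 8 h against 2 h). With normexp and quantile normalization, the genes called were 0 (SEMA3E 8 h) and 0 (cytochalasin D against SEMA3E), and the lists called were 0 (SEMA3E 2 h), 6 (SEMA3E 8 h), 1 (cytochalasin D), 5 (cytochalasin D against SEMA3E) and 0 (SEMA3E 8 h against 2 h). Changes of sign there were Actg1 -0.0897, Mlana -0.0129 and Pmel -0.0693 (SEMA3E 2 h), Dip2b 0.0123 (cytochalasin D), Mical2 0.0433 (cytochalasin D against SEMA3E), Actg1 0.0101, Pmel 0.10 and Tyrp1 0.0248 (SEMA3E 8 h against 2 h). With the mean of a gene's probes, the genes called were 2 (SEMA3E 8 h). Opposite in sign there were Actg1 -0.57 (SEMA3E 2 h), Mitf -0.62 and N4bp2l2 -0.18 (cytochalasin D against SEMA3E), Actg1 0.66 (SEMA3E 8 h against 2 h). With outlier spots kept, the genes called were 0 (cytochalasin D against SEMA3E). Turned in sign there were Tagln2 -4.49 (SEMA3E 8 h), Tagln2 0.54 (cytochalasin D against SEMA3E).

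With no filter, the genes called were 0 (SEMA3E 8 h) and 0 (cytochalasin D against SEMA3E), and the lists called were 11 (SEMA3E 2 h), 13 (SEMA3E 8 h), 1 (cytochalasin D), 8 (cytochalasin D against SEMA3E) and 2 (SEMA3E 8 h against 2 h). With the strict filter, the genes called were 0 (SEMA3E 8 h) and 0 (cytochalasin D against SEMA3E), and the lists called were 2 (SEMA3E 2 h) and 3 (cytochalasin D against SEMA3E). With every probe as its own unit, the genes called were 0 (cytochalasin D against SEMA3E). With the 75th percentile over all probes, the genes called were 0 (cytochalasin D against SEMA3E), and the lists called were 0 (SEMA3E 2 h). With the GC trend removed, the genes called were 2 (SEMA3E 8 h) and 0 (cytochalasin D against SEMA3E). With an intensity trend, the genes called were 0 (SEMA3E 8 h). With only the 2 groups fitted, the genes called were 0 (SEMA3E 8 h) and 0 (cytochalasin D against SEMA3E). With an estimated correlation, the lists called were 0 (SEMA3E 2 h), 0 (SEMA3E 8 h), 0 (cytochalasin D against SEMA3E) and 0 (SEMA3E 8 h against 2 h). The correlation of the 2 treatments at 8 h, 0.19, was 0.49 with no filter, and between -0.0071 (without cytochalasin D replicate 1) and 0.61 (without control replicate 2) when an array was left out, against 0.41 and 0.67 in simulations of unchanged groups with these arrays left out.

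Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 0 to 417 genes (SEMA3E 2 h), 0 to 2 (SEMA3E 8 h), 0 to 1 (cytochalasin D), 0 to 0 (cytochalasin D against SEMA3E) and 0 to 460 (SEMA3E 8 h against 2 h). The lists called ranged from 0 to 3, 1 to 8, 0 to 1, 1 to 2 and 1 to 4 in the same order. Without SEMA3E 2 h replicate 1, the array without which the counts were 417 and 460, the group rests on replicate 2, which had 214 outlier spots against 6 to 24 on the other arrays. Newly passed were Actb, H1f4, Kcnq1ot1, Myc, Palld, Rab27a, Rmrp, Sema4g and Sema5b after normexp, and Patj, Rab27a and Rmrp with the median of all probes (SEMA3E 2 h). Of the normexp calls 3391 of 3431 were higher, with a median of all genes of 0.39, and 0 genes passed with normexp and quantile normalization. The normexp calls of higher genes therefore do not single those genes out. Rn18s passed with the latter (cytochalasin D against SEMA3E), as did Rab27a (SEMA3E 8 h against 2 h). Ccdc70 passed with the mean of a gene's probes, the GC trend removed, the deposited table and the replicate block, Cfap57 with the last 2 and Apobr with the block (SEMA3E 8 h). From the table Ccdc70 passed too (cytochalasin D against SEMA3E), and Catsperg2 (SEMA3E 8 h against 2 h). Without SEMA3E 2 h replicate 1, H1f4, Kcnq1ot1, Myc, Patj, Rab27a, Rmrp and Srf passed (SEMA3E 2 h), and Catsperg2, Ccdc70, H1f4, Ovca2, Rab27a and Srf (SEMA3E 8 h against 2 h). Of the 187 pairs of a gene and a comparison, 32 had a sign that turned when 1 array was left out. Itga5 ranged from -0.0402 to 1.56 with cytochalasin D, Myh9 from -0.13 to 1.56 at SEMA3E 8 h, each lowest without control replicate 1 and highest without control replicate 2, and Srf from -2.13 without SEMA3E 2 h replicate 1 to 0.0286 without replicate 2 at SEMA3E 2 h.

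Replicate numbers may stand for cultures handled together, but deviations of arrays with the same number correlated between -0.15 and 0.14 over the 6 pairs of groups, with 2 over 0.1. With the replicate block, the genes called were 7 (SEMA3E 8 h) and 0 (cytochalasin D against SEMA3E), and the lists called were 0 (SEMA3E 2 h). The planned block on slide or scan date was not run, since there was only 1 slide and 1 scan date.

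Signal over background limits the weakest genes most, with 37.8% to 48.2% of spots well above it. Catsperg2, Ccdc70, Cfap57 and Apobr were above background on neither control array, so their folds rest on signals under background. Catsperg2 at SEMA3E 8 h ranged from 0.32 to 3.79 log2 units over the 22 alternatives, lowest with normexp and quantile normalization, as the added offset shrinks dim signals by construction.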

Other observations

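The Mitf probes and the genes named as examples were chosen after their values were seen, while the gene lists were fixed before.

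Stress, p53 and lipid genes had values above 0 more often than below at 8 h of SEMA3E, and none of these 4 lists passed. Of 21 p53 targets 17 lay above 0 (median 0.31, shift 0.34, adjusted p = 0.189), with the membrane protein gene Perp at 1.39 ± 0.33 (SE). Of 27 lysosome and autophagy genes 25 lay above 0 (median 0.15, shift 0.06, adjusted p = 0.354), with the autophagosome gene Map1lc3b at 0.72 ± 0.29. The unfolded protein and ATF4 response had 18 of 24 above 0 (median 0.21, shift 0.19, adjusted p = 0.421), with Ddit3 at 1.86 ± 0.66, and cholesterol synthesis 19 of 24 (median 0.21, shift 0.13, adjusted p = 0.344), with Dhcr7, the last enzyme of that pathway, at 0.86 ± 0.33. With cytochalasin D relative to SEMA3E, 19 of 24 cholesterol synthesis genes lay below 0 (median -0.29, shift -0.22, adjusted p = 0.209) and the regulator Srebf2 at -1.27 ± 0.40. All genes had a median of 0.12 at 8 h of SEMA3E and of -1.04 after scaling to the median of all probes, so that the signs of these list medians depend on the scaling. The median of all probes is a dim signal, since 37.8% to 48.2% of spots were well above background. The median of all genes was -0.04 with quantile normalization and -0.10 with the 75th percentile over all probes. It was -0.003 with the GC trend removed, a step that also centres each array.

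At 2 h of SEMA3E, 10 of 12 TGF-beta and BMP targets lay below 0 (median -0.48, shift -0.50, adjusted p = 0.172), although Tgif1, with the smallest p of the list, was at 1.14 ± 0.41. YAP-TAZ targets had 12 of 18 below 0 at 2 h (median -0.14, shift -0.29, adjusted p = 0.172) and at 8 h (median -0.16, shift -0.30, adjusted p = 0.118). Hypoxia and glycolysis genes had 19 of 27 above 0 at 2 h (median 0.28, shift 0.26, adjusted p = 0.172), with the stress gene Ddit4 at 2.49 ± 0.75. Immediate early genes had a median of -0.17 and a shift of -0.43 at 2 h (adjusted p = 0.172), and 16 of 20 lay above 0 with cytochalasin D (median 0.27, shift 0.37, adjusted p = 0.392). In the focal adhesion list the integrin gene Itga1 was at -1.50 ± 0.42 at 2 h, and among heat shock proteins Hspa8 was at -1.07 ± 0.41.

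Further lists had shifts at SEMA3E 2 h, SEMA3E 8 h and cytochalasin D against control, in this order, that did not pass. They were -0.19, 0.00 and 0.09 for focal adhesion and extracellular matrix. For tubulins and microtubule proteins they were 0.06, -0.14 and 0.05, for G2 and mitosis -0.15, -0.06 and 0.06, and for heat shock proteins -0.03, -0.13 and 0.07. For NF-kappaB targets and cytokines they were 0.21, -0.07 and 0.09, and for dedifferentiated melanoma markers 0.34, -0.19 and 0.24. For the interferon response they were -0.01, 0.13 and -0.04, with 17 of 23 genes above 0 at 8 h of SEMA3E. Median and shift differed in sign for heat shock proteins (0.04 and -0.03) and the interferon response (0.10 and -0.01) at 2 h. They also did at 8 h of SEMA3E for tubulins (0.01 and -0.14), G2 and mitosis (0.09 and -0.06), NF-kappaB targets (0.13 and -0.07) and dedifferentiated markers (0.07 and -0.19), and with cytochalasin D for the interferon response (0.04 and -0.04). Heat shock proteins had a mean of 0.07 at 8 h of SEMA3E against a median of -0.07. In the comparison of the treatments the semaphorin family had a median of -0.24 and a shift of 0.03.

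Probes of Mitf did not move together. The brightest read between 3.03 and 3.64 on all 8 arrays, while 2 others read between 0.17 and 0.69 on control replicate 1 and both SEMA3E 2 h arrays and between -1.84 and -3.38 on the other 5. Those 2 thus differed between the control arrays themselves. The Mitf differences given above are of the brightest probe, except where the mean of a gene's probes or the deposited table is named. Of 3279 genes with at least 2 probes above background on all arrays, 174 (5.31%) had probes that disagreed by over 2 log2 units in the difference between the controls.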
